A study of Mus musculus with 2 samples.

How the data were processed

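MicroRNA-seq libraries from the adrenal glands of female B6CASTF1/J mice aged 36 days were analysed, 1 group of 2 libraries. The labels number them as biological replicates 1 and 2 and describe separately numbered females, but give both the same donor identifier. They were treated as biological replicates, and whether the SD is a spread between animals is therefore not certain. The labels give total RNA as the starting material. The deposited tables hold raw read counts per miRNA gene in 3 columns, with 4 summary entries that name no gene. The notes deposited with each library give the mm10 assembly and GENCODE M21 annotation. The aligner, the counting tool and any trimming of adapters are not given in the sources used here. No header names the 3 columns. The counted, no-feature and ambiguous reads add up to the same total in each column, so the columns were read as 1 set of reads counted without strand, on the sense strand and on the antisense strand. The sense column was the one that held nearly all reads of genes with no partner on the other strand. The summary entries (unmapped, mapped to several places, no miRNA gene, ambiguous) were left out of library sizes and tests, and the report gives their shares. Reads that mapped to several places are in no gene's count, so levels of genes with near-identical copies are uncertain. Counts are of reads, and PCR duplicates cannot be told from separate molecules.

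All 2202 gene identifiers matched miRNA genes of GENCODE M21, which gave names, positions, host genes on the same strand and hairpin sequences. Host genes were protein-coding and long noncoding genes that contain the whole hairpin. Levels are CPM, the sense count over the library's total of sense miRNA counts, times 1000000. A gene was detected with at least 10 counts in both libraries. The floor for a count of 0 was 3 counts. Shares in a single library have 95% Wilson intervals, which cover counting error only. The depth differed by 1.78-fold, so replicate 2 measured low genes less precisely, with 1 count worth 0.185 CPM in replicate 1 and 0.330 CPM in replicate 2.

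Ratios between the libraries used TMM effective library sizes (edgeR 4.0.16 in R 4.3.3), a prior of 0.5 counts and genes with at least 10 counts over both libraries. Each gene's counts were compared by an exact two-sided binomial test (scipy 1.17.1), with Benjamini-Hochberg adjustment (statsmodels 0.14.6) and a threshold of 0.05. With no second group there was no contrast between conditions. The pooled spread was edgeR's common dispersion with an intercept only, given as a coefficient of variation, and the limit for pairs of genes assumes that spread for each gene. A group's median log2 ratio was placed among 10000 random groups of the same size drawn from 10 abundance bins, for groups with at least 3 genes measured. This describes the libraries and gives no p-value. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

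Before the data were examined, 22 gene groups, the design, most alternatives and the rule for named genes were fixed. The groups were the families let-7, miR-30, miR-10 with miR-100 and miR-125, miR-15/miR-16, the miR-17 to miR-92 clusters, miR-23 with miR-27 and miR-24, miR-26, miR-29 and miR-181. They also included genes reported after ACTH, neural and neuroendocrine, endothelial, mesenchymal, red-cell, white-cell, epithelial, kidney and gut, hepatocyte, muscle, X-linked testis, Dlk1-Dio3 and other imprinted genes. One member of the red-cell group, Mir486b, had no match in the annotation. The rule named the 20 genes with the highest mean CPM, up to 4 detected members of each group with the highest mean CPM, all members of groups of at most 3, and the 5 largest ratios in each direction among called genes with at least 100 counts over both libraries. Genes named outside it are marked in the text.

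The alternatives set in advance were other count minimums and pseudocounts, total counts and DESeq2 1.42.0 size factors in place of TMM, DESeq2's dispersion, counts without strand, the deeper library thinned to the depth of the shallower, a 2-fold minimum, Spearman's rho, leaving out each library and leaving out the most abundant gene. Chosen after seeing the data were the common dispersion as the error of the test, the removal of the trend with hairpin GC content, the neighbour test without Dlk1-Dio3 and the alternatives for single genes. The tests of explanations in the closing section used genes with at least 100 counts over both libraries for ratios, and 10000 permutations. Related sequence meant a shared stretch of 12 bases at loci at least 1 Mb apart, neighbours lay within 10 kb on the same strand, and a copy elsewhere meant a shared stretch of 20 bases.

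The steps were tested on simulated data with the real genes and depths. In the step on single genes, with counting noise alone, 200 genes were given a known change. Of the 438 genes with enough counts to be tested, 194 were changed and 244 were not. Of all genes given a change, whether tested or not, it recovered 64% of changes of 1.5-fold and 80% of 3-fold, 100% in the right direction, and called 4 of 244 unchanged genes and 0 genes when none was changed. In the step on groups, run on 433 genes, groups of 8 genes came out in the outer 5% in 3% of 100 draws when unshifted and in 59% when shifted by 1 on the log2 scale. These genes were drawn at random and given independent spreads. The 3% therefore does not give the rate for real groups of neighbours or relatives, whose ratios can move together. Both steps used total counts in place of TMM.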

Results

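MicroRNA-seq, the sequencing of RNAs short enough to be mature microRNAs (miRNAs), was used to profile the adrenal glands of female B6CASTF1/J mice aged 36 days. This strain is a first-generation hybrid between a common laboratory strain and a wild-derived strain. The adrenal gland joins a steroid-producing cortex to a medulla of catecholamine-secreting chromaffin cells. The samples formed 1 group of 2 libraries, which the labels give as biological replicates taken from separately numbered females. The labels also give both libraries the same donor identifier, so it is not certain that the replicates are 2 animals. No second tissue, age, sex or treatment was included, so the comparisons that the design allows were those between miRNA genes within the gland and those between the 2 libraries. Replicate 1 held 13973580 reads and replicate 2 held 7530945. Reads on the sense strand of an annotated miRNA gene numbered 5397603 in replicate 1, or 38.6% (95% Wilson interval 38.6 to 38.7%), and 3029977 in replicate 2, or 40.2% (40.2 to 40.3%). Reads that mapped to several places took 28.5% and 30.6%, unmapped reads took 26.0% and 22.3%, and reads at 1 place outside the miRNA genes took 6.88% and 6.86%. Levels below are normalised read counts (CPM), a gene's sense count for each 1000000 sense miRNA counts of the library, as mean ± SD with n = 2 libraries.

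The adrenal miRNA profile was led by Mir126a, a gene best known from endothelial cells, and by members of the let-7 family, which regulates developmental timing. Mir126a (chromosome 2, 26591357 to 26591429, plus strand, in an annotated exon of Egfl7) had 101247 ± 45201 CPM. Mirlet7g (chromosome 9, 106178840 to 106178927, plus strand, intron of Wdr82) had 96023 ± 7753 CPM, and Mirlet7b (chromosome 15, 85707319 to 85707403, plus strand, exon of the noncoding gene Lncppara) had 65047 ± 5176 CPM. Mir378a (chromosome 18, 61397835 to 61397900, minus strand, intron of Ppargc1b, a coactivator of mitochondrial genes) followed with 61402 ± 8455 CPM. Mir10a (chromosome 11, 96317165 to 96317274, plus strand, within none of the same-strand genes considered) had 52400 ± 12656 CPM. All positions are in mm10 with GENCODE M21 annotation.

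The order of the leading genes was not the same in both libraries. Mir126a reached 133209 CPM (95% Wilson interval 132922 to 133495) in replicate 1, above the 90540 CPM of Mirlet7g (90298 to 90782). In replicate 2 it had 69285 CPM (68999 to 69571), below the 101505 CPM of Mirlet7g (101166 to 101846). The means of these 2 genes therefore could not be ranked against the spread between libraries. Mirlet7i, another let-7 gene, had 41501 ± 3175 CPM, Mir143 of smooth muscle had 41485 ± 17671, Mir23a had 40550 ± 10914, Mir26b had 34227 ± 5672 and Mir23b had 33302 ± 7832. These 10 genes held 56.7% ± 2.38 of the sense miRNA counts, and the top 20 held 76.5% ± 2.53. The second 10 ran from Mir21a at 26772 ± 11071 CPM through Mir22, Mir375, Mir10b, Mir139, Mir322, Mir99a, Mirlet7d and Mir127 to Mir30e at 11770 ± 1073 CPM. Of the 20 genes highest in each library, 18 were shared. Among the 190 pairs of the top 20 genes, 159 had the same order in both libraries. The geometric means differed by more than 2.26-fold in 77 pairs, the limit that the pooled spread between the libraries sets for 2 genes. That spread leaves out any yield of library preparation that depends on sequence and is shared by both libraries. These are therefore orders of read counts, and amounts of miRNA may be ordered otherwise.

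**Figure D1:**
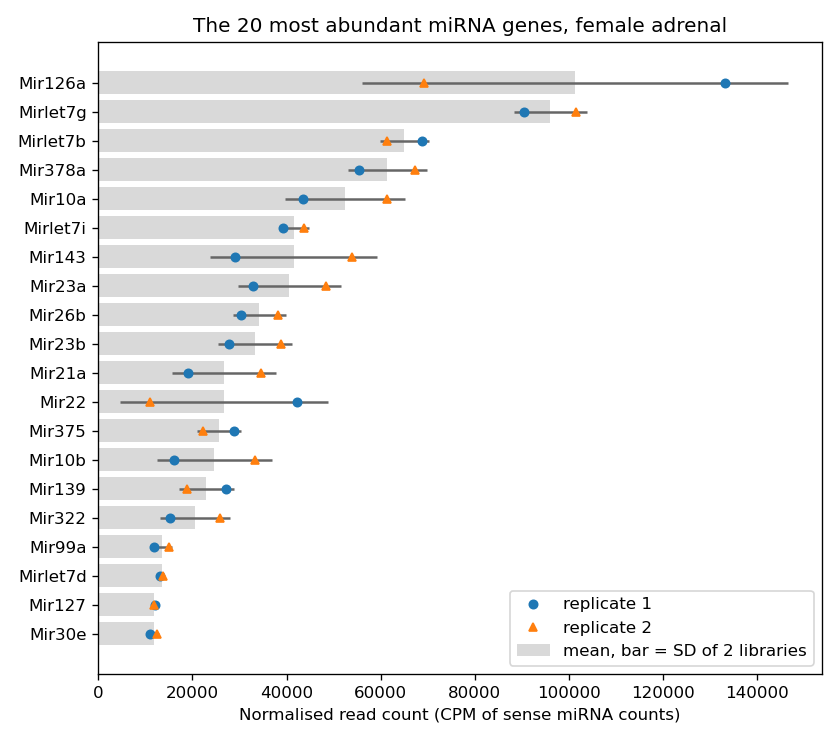
Normalised read counts, in CPM, of the 20 miRNA genes with the highest mean among reads that mapped to 1 place. Replicate 1 is shown as circles, replicate 2 as triangles, the mean of the 2 libraries as grey bars and their SD as lines. Mir126a lies at 133209 CPM in replicate 1 and 69285 CPM in replicate 2, while Mir127 has nearly equal values of 12005 and 11758 CPM.

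Of 2202 annotated miRNA genes, 339 had at least 10 counts in both libraries, and 1433 (65.1%) had a count of 0 in both. A count of 0 allowed a level of up to 0.556 CPM in replicate 1 and 0.990 CPM in replicate 2. Intervals and these limits cover counting error only. Of the detected genes, 79 share at least 20 bases with another miRNA locus, among them Mir378a, Mir23a, Mir23b, Mir27a, Mir27b, Mir411, Mir376c, Mir26a-1 and Mir199b. Reads that mapped to several places were counted for no gene, so these levels are uncertain. They numbered 3984008 in replicate 1 and 2302439 in replicate 2, and how many came from miRNA genes is not known. Genes with copies elsewhere could therefore rank higher than shown, and the ranking and the top 10 share hold for counted reads only.

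By family, let-7 had the largest share of counted reads among the groups examined, with 12 of 12 genes detected and 23.7% ± 0.448 of the counts. Reads that mapped to several places are in none of these shares. Genes sharing at least 20 bases with another locus were 6 of 12 in let-7 and 6 of 6 in the miR-23, miR-27 and miR-24 clusters. They were 3 of 4 in miR-29 and 4 of 6 in miR-181, so the family shares and their order are uncertain. The miR-10, miR-99/miR-100 and miR-125 families, of which Mir10a and Mir10b lie in Hox gene clusters, held 10.5% ± 2.24 with 8 of 8 genes detected. The clusters of miR-23, miR-27 and miR-24 held 8.05% ± 1.86, mostly in Mir23a and Mir23b, while Mir27b had 5315 ± 73.8 CPM. The miR-26 family held 3.43% ± 0.569, all but 86.4 CPM of it from Mir26b among reads that mapped to 1 place. Mir26a-1 and Mir26a-2 share at least 20 bases, so this does not show that miR-26a was low. The miR-30 family held 3.43% ± 0.255, with Mir30e, Mir30a and Mir30d between 10305 and 11770 CPM. The miR-15/miR-16 family held 2.97% ± 0.0142, led by Mir322 at 20589 ± 7447 CPM. This small SD is of a total whose members moved in opposite directions and does not show that they were reproducible. Mir322 had 15323 CPM in replicate 1 and 25855 in replicate 2, while Mir195a had 6372 and 959. The clusters running from miR-17 to miR-92, first known from proliferating cells, held 0.959% ± 0.0111, led by Mir93 and Mir17. Here too the small SD is of a total whose members moved in opposite directions. Mir93 had 2956 CPM in replicate 1 and 3874 in replicate 2, while Mir92-1 had 1063 and 496. The miR-29 family, which targets collagen messages, held 0.842% ± 0.203, and the miR-181 family held 0.237% ± 0.0258.

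The groups fixed for the cell types of the gland differed widely in level. The endothelial pair Mir126a and Mir126b held 10.1% ± 4.52, with Mir126b at only 5.00 ± 0.532 CPM. The group for smooth muscle, pericytes and fibroblasts held 4.57% ± 1.96, mostly from Mir143, and Mir145a, its neighbour on chromosome 18, had 3254 ± 2833 CPM. Neural and neuroendocrine miRNAs, chosen with the medulla in mind, held 2.93% ± 0.441. Mir375, known from endocrine cells, made up most of this at 25584 ± 4721 CPM, followed by Mir7b at 2790 ± 312 and Mir137 at 469 ± 47.7, whereas all 3 genes for miR-124, the neuronal miRNA, had 0 counts. Those 3 share at least 20 bases with each other, so their reads could be left out of the counts and the 0 counts do not show absence. The genes reported in rat adrenal after the pituitary hormone ACTH held 0.354% ± 0.120, led by Mir27a, Mir214, Mir182 and Mir132. Of the miRNAs of blood cells, the white-cell group held 0.227% ± 0.0487 (Mir342 at 576 ± 10.4 CPM) and the red-cell group 0.0893% ± 0.0448 (Mir451a at 556 ± 235 CPM). The epithelial group held 0.230% ± 0.202, almost all of it Mir203 at 2256 ± 2029 CPM. The hepatocyte gene Mir122 had 825 ± 959 CPM, or 0.0825%, the muscle group 0.0518% ± 0.00371 and the kidney and gut group 0.00965% ± 0.00553. Genes sharing at least 20 bases with another locus were 16 of 20 in the neural and neuroendocrine group and 5 of 9 in the muscle group. They were 3 of 7 in the group for smooth muscle, pericytes and fibroblasts and 2 of 4 in the kidney and gut group. These shares are therefore uncertain too.

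The miRNAs of the imprinted Dlk1-Dio3 locus on chromosome 12 are transcribed from the maternal allele. Of the 46 genes in the group fixed for this locus, 43 were detected. Together the 46 genes held 4.04% ± 0.196 of the counts. The group leaves out some annotated miRNA genes of the locus, so these values are of the group. Mir127 (109592846 to 109592915, plus strand) led with 11882 ± 175 CPM, ahead of Mir411 at 5961 ± 49.6, Mir379 at 5373 ± 760 and Mir541 at 3511 ± 393 CPM. Of the other imprinted genes examined, Mir335 in Mest had 6308 ± 2527 CPM, Mir483 in Igf2 had 11.2 ± 10.7 CPM, and Mir675 in H19 had 4 counts in replicate 1 and 1 in replicate 2. None of the 13 genes of an X-linked cluster known from testis reached 10 counts in both libraries, and 7 had 0 counts in both.

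Strand decided whether several abundant genes were seen. Mir126a had 719007 and 209931 sense counts in replicates 1 and 2, but only 11 and 3 counts when the strand of the reads was ignored. Mir378a had 299149 and 204161 sense counts and Mir30e had 59435 and 37964, and both genes had 0 counts in each library without strand. Of the genes with at least 1000 sense counts in both libraries, 12 had under 5% of them without strand. The other 9, listed after their values were seen, were Mirlet7e, Mir191, Mir337, Mir376a, Mir409, Mir497, Mir142, Mir451a and Mir299a. An annotated miRNA gene lies on the opposite strand at each of the 12, such as Mir126b at Mir126a and Mir30f at Mir30e. Without strand, 1207168 reads in replicate 1 and 516801 in replicate 2 were ambiguous between genes. Antisense counts made up 16.4% ± 2.62 of the counts on both strands over all genes. Nearly all of them are sense reads of a partner gene counted a second time. Mir126b, for example, had 718996 antisense counts in replicate 1, so the 16.4% does not measure antisense RNA. At genes with no miRNA gene on the other strand the share was 0.0146%. The sense column was chosen by such genes, so a low share there follows from that choice.

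The comparison of the 2 libraries asked how closely their adrenal profiles matched. Across the 434 genes with at least 10 counts over both libraries, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.976. The ratio of a gene between the libraries, scaled by TMM, was under 2-fold for 322 genes and at least 4-fold for 30, with a median size of 1.49-fold. The pooled coefficient of variation was 41.5%. If every gene had that spread and no counting error, 95% of the ratios between 2 libraries would lie within 3.16-fold. The 30 genes at 4-fold or more are more than this allows, so it does not describe all genes. An exact two-sided binomial test with Benjamini-Hochberg adjustment called 254 of the 434 genes against counting error alone, 131 higher in replicate 1 and 123 higher in replicate 2. Scaling to total counts moved all ratios by 0.30 on the log2 scale and gave 189 genes higher in replicate 1 and 83 higher in replicate 2. The test compares these libraries and not conditions, and with the pooled spread in place of counting error 3 genes were called (Mir215, Mir26a-1 and Mir122, of which Mir215 was named after its values were seen). Mir215 had 23 counts in replicate 1 and 0 in replicate 2, or 3.49-fold higher with TMM when the 0 is set to the floor of 3 counts. The log2 ratio also followed the GC content of the hairpins, with a Spearman's rho of 0.348 across 284 genes with at least 100 counts over both libraries.

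**Figure D2:**
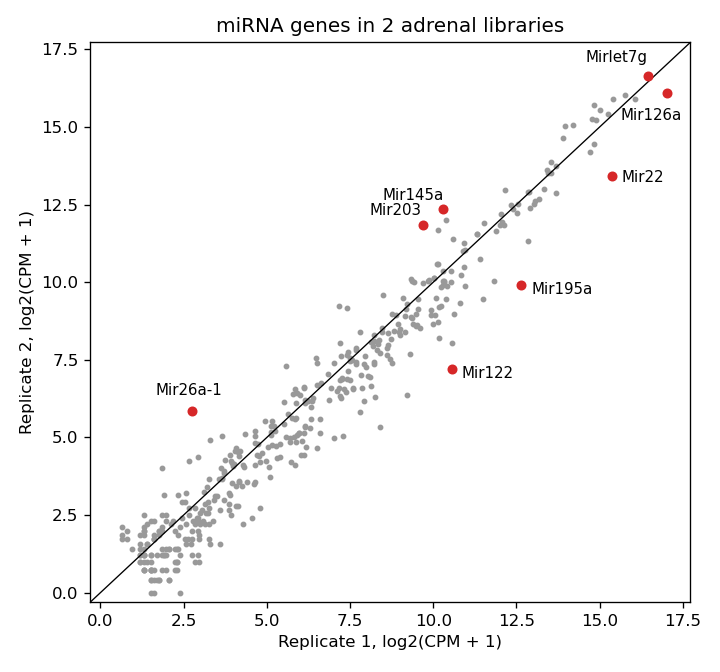
Levels of the 434 miRNA genes with at least 10 counts over both libraries, as log2(CPM + 1), with replicate 1 on the horizontal axis and replicate 2 on the vertical axis. The line marks equal CPM, and the genes in red are named: Mir122, Mir195a and Mir22 lie towards replicate 1, and Mir26a-1, Mir203 and Mir145a towards replicate 2.

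Among the called genes with at least 100 counts over both libraries, replicate 1 was higher by the largest ratios in Mir122 (8.33-fold), mmu-mir-3535 (6.92-fold), Mir301 (5.87-fold), Mir195a (5.39-fold) and Mir214 (4.70-fold). Mir122, the main miRNA of hepatocytes, had 1503 CPM (95% Wilson interval 1471 to 1536) in replicate 1 and 146 CPM (133 to 160) in replicate 2. Replicate 2 was higher by the largest ratios in Mir26a-1 (12.2-fold, 31 against 174 counts), Mir203 of the epidermis (5.54-fold), Mir376c (5.22-fold), Mir145a (5.18-fold) and Mir196b of a Hox cluster (4.23-fold). Mir26a-2, which shares at least 20 bases with Mir26a-1, went the other way (378 against 120 counts, log2 ratio 0.52, adjusted p = 0.00109 in the exact binomial test), so the ratio of Mir26a-1 is uncertain. Among the top 20 genes, Mir22 differed most, with 42308 CPM in replicate 1 and 10990 in replicate 2 (3.12-fold). Mir10b (2.56-fold), Mir143 (2.30-fold), Mir21a (2.25-fold) and Mir322 (2.08-fold) were higher in replicate 2. Mirlet7b and Mir127 were higher in replicate 2 by 1.10-fold and 1.21-fold with TMM, and higher in replicate 1 with total counts. Mir375 differed by 1.05-fold, and its call was lost with DESeq2 size factors (exact binomial test, adjusted p = 0.661).

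Of the 18 gene groups with enough members, 6 had a median ratio outside the middle 95% of 10000 random groups of like abundance. By chance 0.9 would be so for independent groups of independent genes. The random groups were drawn gene by gene, while several groups hold neighbours, such as Mir144 with Mir451a and Mir143 with Mir145a. Where neighbours move together, more than 0.9 would be so by chance. In the miR-15/miR-16 family 7 of 8 genes were higher in replicate 1, with Mir195a, Mir15a (2.77-fold) and Mir15b (2.54-fold) in front and Mir322 the exception. Its median log2 ratio of replicate 1 over replicate 2 was 0.71 (percentile 98.9). The red-cell group was higher in replicate 1 for 3 of 3 genes, Mir451a, Mir144 (2.09-fold) and Mir486 (2.40-fold), with a median of 1.06 (percentile 98.3). The white-cell group was higher in replicate 2 for 5 of 5 genes with TMM, from Mir142 (2.68-fold) to Mir342 (1.20-fold), with a median of -0.71 (percentile 1.26). With total counts Mir342 (adjusted p = 0.469) and Mir155 (adjusted p = 0.565) lost their calls in the exact binomial test. The log2 ratio of Mir342 then turned to 0.037, towards replicate 1. In the muscle group 3 of 4 genes were higher in replicate 2, Mir206, Mir499 and Mir208b, with a median of -1.11 (percentile 1.74). The call of Mir206 was lost with total counts (exact binomial test, adjusted p = 0.259). The group of Mir10a, Mir10b and their relatives had 5 genes higher in replicate 2 and 3 higher in replicate 1, with a median of -0.62 (percentile 1.5). In the group for smooth muscle and fibroblasts Mir143, Mir145a and Mir199b were higher in replicate 2, and Mir214 in replicate 1, with a median of -0.89 (percentile 0.85). This median was -0.16 (percentile 27.2) without Mir143. All but the miR-15/miR-16 median came inside the middle 95% under at least 1 other setting.

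The medians of the other 12 groups lay inside the middle 95%. They were -0.18 for let-7, -0.30 for miR-30, 0.01 for the miR-17 to miR-92 clusters, -0.34 for miR-23, miR-27 and miR-24, -0.64 for miR-26, 0.56 for miR-29 and 0.26 for miR-181. The others were 0.05 for the ACTH-linked genes, 0.00 for the neural and neuroendocrine genes, -0.62 for the epithelial genes, 1.22 for the kidney and gut genes and -0.04 for the Dlk1-Dio3 locus. Another scaling turned the sign for let-7, miR-30, the miR-17 to miR-92 clusters, the ACTH-linked genes, the neural and neuroendocrine genes and Dlk1-Dio3. The endothelial, hepatocyte, X-linked and other imprinted groups had fewer than 3 genes with enough counts.

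**Figure D3:**
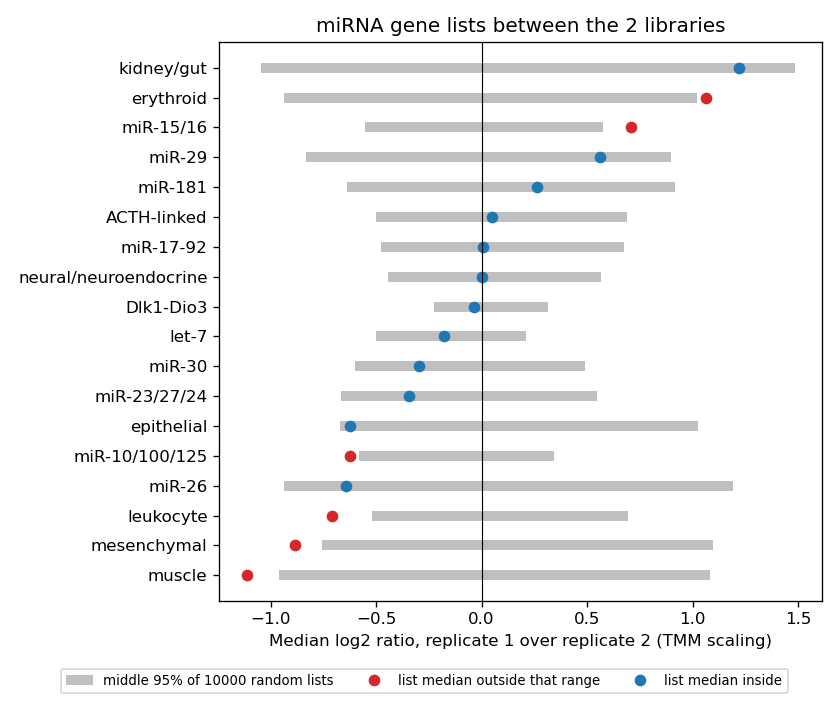
Median log2 ratio of replicate 1 over replicate 2 for 18 gene groups (points), with the middle 95% of 10000 random groups of the same size and like abundance (grey bars). The 6 red points lie outside their bars, from -1.11 for the muscle group to 1.06 for the red-cell group, and the blue points lie inside.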

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

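Mir203 (chromosome 12, 112130880 to 112130955, plus strand) had antisense counts of 444 in replicate 1 and 374 in replicate 2, against sense counts of 4435 and 11184. It was singled out because the antisense column is outside the main measurement, GENCODE M21 has no miRNA gene on the other strand there, and both values lie above the 3 counts that a count of 0 allows. No other gene without an annotated partner had at least 10 antisense counts in both libraries.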

How the results depend on the processing

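The tests with the common dispersion, the GC trend and single genes were chosen after the data were seen. The top 10 share moved by less than its SD and the pooled coefficient of variation by under 10% in the alternatives run. Leaving out a library cannot move a mean of 2 libraries beyond its SD, so it tests no level here. The cause of the changes below was not tested unless a smaller set of genes or members explains it. Genes detected numbered 569 at 1 count and 219 at 100 counts in both libraries. Pearson's r was 0.968 with a pseudocount of 0.1, 0.983 with no filter and 0.961 at 100 counts, and Spearman's rho was 0.965. Calls between the libraries numbered 85 with a 2-fold minimum and 3 with the common dispersion, which comes from these same differences. The antisense share was 9.25% over detected genes. Without its most abundant member, the level fell to 140928 CPM for let-7, 22499 for miR-30, 52983 for miR-10 and relatives, 9131 for miR-15/miR-16, 6175 for the miR-17 to miR-92 clusters, 39926 for miR-23 and relatives, 86.4 for miR-26, 1297 for miR-29 and 1360 for miR-181. It fell to 3689 for neural, 5.00 for endothelial, 4174 for mesenchymal, 337 for red-cell, 1637 for white-cell, 44.7 for epithelial, 34.2 for muscle, 28563 for Dlk1-Dio3 and 11.7 for other imprinted genes. The miR-15/miR-16 level was 29893 CPM with TMM and 29984 with DESeq2 scaling, both beyond its SD, which is small because its members moved in opposite directions. Among group medians, miR-10 and relatives came inside the middle 95% at 100 counts (-0.51), without Mir10a (-0.62) and with the GC trend removed (-0.52). So did the mesenchymal group without Mir143 (-0.16), the red-cell group at 100 counts (1.18), the white-cell group at 100 counts (-0.59) and without strand (-0.48), and the muscle group with the GC trend removed (-0.93). Groups that moved outside were miR-26 (-0.89) and miR-29 (0.87) with the GC trend removed, and the epithelial group without strand (-0.66) and with that trend removed (-0.72), while without Mir203 the epithelial median turned to 0.067 (percentile 34.5). Total and DESeq2 scaling move all ratios alike, so they cannot change a group's place and test nothing there. Of the called single-gene ratios, 3 reversed and stayed called with total counts, to 0.16 for Mirlet7b, 0.030 for Mir127 and 0.23 for Mir541. The sign also turned, with the call lost, for Mir411 (0.017), Mir27b (0.028) and Mir342 (0.037). Mir379, not called with TMM, turned from -0.012 to 0.29. Of the 79 named genes, 40 changed level by more than their SD without strand. These include genes whose own counts did not change, such as Mirlet7g (488699 in replicate 1 either way). Their CPM rose because the total of miRNA counts fell without strand. It fell from 5397603 to 4190963 in replicate 1 and from 3029977 to 2513602 in replicate 2. Levels near the floor are limited by the depth of replicate 2.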

Other observations

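The tests of a linear GC trend as the whole cause, of genes on the opposite strand and of copies elsewhere were chosen late. The results they explain had been seen by then, as they had for the neighbour test without Dlk1-Dio3. The test of genes on the opposite strand took the place of others whose outcome was fixed in advance, and its bounds were set with its value known. Ratios of some leading genes had been seen before the GC and pair tests were set, and the pair tests were read against their permutation spread only after their values were known.

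Several clustered genes, but not most, had ratios that pointed the same way. Of the 64 neighbour pairs of unrelated sequence outside Dlk1-Dio3, 45.3% had standardized ratios of the same sign. Mir143 and Mir145a, neighbours on chromosome 18, were both higher in replicate 2, with log2 ratios of replicate 1 over replicate 2 of -1.20 and -2.37. Mir195a and Mir497, side by side on chromosome 11, were both higher in replicate 1 (2.43 and 0.78), as were Mir15a and Mir16-1 on chromosome 14 (1.47 and 0.63) and Mir144 and Mir451a on chromosome 11 (1.06 and 0.59). Others parted. Mir322 was higher in replicate 2 (-1.06) and Mir503 of the same X-linked cluster in replicate 1 (0.53), and Mir93 was higher in replicate 2 (-0.69) with Mir106b and Mir25 higher in replicate 1 (1.68 and 0.64). Within the Dlk1-Dio3 group, with TMM scaling, 14 genes were called higher in replicate 1, 16 higher in replicate 2 and 14 were not called. The called genes ranged from Mir665 (1.58) to Mir376c (-2.38). These genes were picked after their values were seen.

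Many genes differed between the 2 libraries (254 of 434 against counting error alone, 3 against the pooled spread between libraries). The SD of the log2 ratio over 284 genes was 0.90 before and 0.85 after the linear trend with hairpin GC content was removed. That trend held 9.48% of the variance, which argues against a linear effect of hairpin GC content as the whole cause. The fall in SD follows from the correlation of the same values, so it is no separate test. A non-linear effect and the GC content of the mature sequence were not tested. A contribution of GC content stayed open: Spearman's rho of the log2 ratio with GC content was 0.348 across genes (permutation p = 0.0001, the smallest that 10000 permutations can give), and 0.338 without Dlk1-Dio3. A yield of library preparation that depends on sequence and a shift in transcription or cell makeup cannot be told apart here: pairs of related sequence at separate loci had a mean product of standardized ratios of 0.161 (111 pairs, permutation p = 0.0405) and neighbours of unrelated sequence one of 0.0117 (306 pairs, permutation p = 0.349). What keeps this open is that the first lies between the bounds set in advance, that the second lies below its bound of 0.05 by less than the permutation SD of 0.0555, and that most neighbour pairs lie in Dlk1-Dio3, without which the value was 0.136 (64 pairs, permutation p = 0.123). The labels give no condition that separates the libraries, so no biological explanation from the design was tested.

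The near absence of 12 abundant genes from the counts without strand went with annotated miRNA genes on the opposite strand. The 12 genes lost 1200451 counts in replicate 1 and 513532 in replicate 2, which is 99.4% of the rise in ambiguous reads (from 0 with strand to 1207168 and 516801 without), while reads of no gene fell by 528 and 426, so ambiguity between overlapping genes accounts for the loss. No biological explanation was tested. The partnered genes held 22.4% of the sense counts in replicate 1 and 17.1% in replicate 2. The choice of strand column could thus move the CPM of many of the named genes through the total, also where their own counts did not change.

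Genes with a near-identical copy elsewhere had low counts next to their cluster mates. In 20 of 24 clusters the genes sharing 20 bases with another locus were lower, with a median log2 difference of -3.59 (permutation within clusters, p = 0.0012). Examples, chosen after their values were seen, are Mirlet7c-2 at 1097 CPM beside Mirlet7b at 65047, Mirlet7a-2 at 119 beside Mir100 at 2181, and Mir29b-1 at 22.6 beside Mir29a at 7119. A candidate explanation is that reads fitting several copies were left out of gene counts, and how many such reads there were is not known. Mature miRNAs of 1 cluster can differ in stability and processing, which was not tested.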
